A study of Drosophila melanogaster with 6 samples.

How the data were processed

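RNA was measured in 6 libraries of whole wandering larvae of Drosophila melanogaster, in the last instar and raised at 25 °C, each from a pool of more than 20 animals, per the labels. The libraries come from 3 genotypes (wild type, depletion of Cmi and depletion of Trr) at 2 stages, called blue gut and clear gut after the colour of the gut. Larvae reared on dyed food keep a blue gut early in wandering and lose it shortly before the puparium forms. Each of the 6 groups holds 1 library. The labels do not name the wild-type stock, and do not say whether it carried the driver used in the depleted larvae. Cmi is another name of the gene Lpt, which stands in the annotation as Lpt.

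Per the labels' extraction protocol, RNA was treated with DNase I, selected with oligo dT, fragmented, copied into cDNA and sequenced on an Illumina HiSeq instrument. The same protocol says that filtered reads were aligned with SOAPaligner/SOAP2. The submitters' processing notes name Bowtie and the genome build dm6, without a version or the step at which Bowtie was used. The tool that counted reads and the annotation behind the genes are not given in the sources used here.

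The deposited table gives RPKM, made by the authors as read counts scaled for gene length and library depth, and a gene length in bases. It holds 15741 entries, of which 2307 have no gene symbol, and 13253 of the gene identifiers (84.2%) were found in the reference annotation, which supplied coordinates. In every column the product of RPKM and length sums to the total that a full count of the listed genes gives, so that the values are scaled to the reads that fell on the genes of the table. A dash was read as 0. Read counts were recovered by finding the depth at which most values become whole reads. At that depth 85.2% to 86.2% of the values per library lay within 0.1 of a whole read, where chance gives 20%. Between 99.99% and 100% lay within 0.1 of a whole read or of a whole read plus 0.5, where chance gives 40%. The recovered depth was 23.1 and 24.2 M reads for wild type at blue gut and clear gut, 23.6 and 25.0 M for Cmi depletion, and 23.3 and 23.9 M for Trr depletion. An entry was marked where the share of libraries with values off whole reads was at least 0.5, among those that could be judged. This marked 2561 entries, 1942 of them tested, and an unmarked entry can still hold some such values. In 1344 entries too few libraries could be judged. Marked genes are not set apart in the main fit, and an alternative leaves out both the marked entries and those not judged.

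A floor of 3 reads corresponds to 0.0777 to 0.0842 RPKM at the median gene length of 1543 bases, and it was applied per library where a fold was taken against 0 reads. Counting intervals of a ratio are exact (Clopper-Pearson) 95% intervals of the share of reads that fell in one of the compared libraries. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules and each pool of animals was sequenced once.

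Fold changes were computed on the scale of log2(RPKM + 1), which understates the change of genes with low values. The test used limma 3.58.1 in R 4.3.3 with statmod 1.5.0 (lmFit, then eBayes with trend and robust), fitted to genes with a mean of at least 1 RPKM over the 6 libraries, 11467 in number. The model holds genotype and stage as additive terms, which leaves 2 residual degrees of freedom, with a prior of 2.75 and a median residual SD of 0.18. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, at 0.05. Since no group has a replicate, the residual is the extent to which a genotype's effect differs between the stages, and not the spread between pools of larvae. Within a stage no p-value can be had, and ratios are given with their counting intervals. The words rose, fell and changed are kept for genes that limma called, and for lists that camera called.

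The comparisons were Cmi depletion with wild type, Trr depletion with wild type, Trr with Cmi depletion, and clear gut with blue gut. Genes that differed 2-fold in the same direction at both stages were counted beside the number that independent lists would share. Correlations were taken across genes, which are not independent replicates. The value expected from a shared wild-type library alone came from 100 simulated draws with no effect of genotype. The 35 gene lists were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the 35 lists of a comparison. With an estimated correlation camera rests on the 2 residual degrees of freedom, so hardly any list can pass. A simulated list of raised genes had an unadjusted camera p of 1.33e-35 with the preset and 0.00493 with an estimated correlation. A call lost in this way is thus little evidence against a list, while the preset can overstate a list whose members vary together. Camera compares a list with all other genes, so a list can be called lower while its median lies above 0. Within a stage, a list's median was ranked among 10000 random lists of the same size with matched expression, and the percentile is given. An alias of roX2 in the lists matched an unrelated gene and was dropped, and roX1 matched no entry, so the roX genes are not analysed here.

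The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule names Lpt, trr and the other COMPASS subunits, and the 10 highest and 10 lowest genes per depletion by the smaller of the ratios at the 2 stages. It adds the 8 highest and 8 lowest genes for stage over the 3 genotypes, the 5 highest and 5 lowest for Trr against Cmi depletion, and the 4 highest and 4 lowest differences between stages per depletion. From each gene list it takes up to 4 members with the largest mean ratio, and EcR, br, Eip74EF and Eip75B in any case. Entries without a symbol are counted but not printed. The RNA interference genes other than Dcr-2 were named after their values were seen.

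The alternatives were a pseudocount of 0.1, no filter or a mean of at least 5 RPKM, median-ratio scaling, quantile normalization, eBayes without trend and robust, an adjusted p of 0.10, a minimum of 2-fold, models without the stage or the genotype term, fits to the libraries of 1 depletion and wild type alone, each library left out in turn, and a threshold of 1.5-fold. Added after seeing the data were fits to entries with a gene symbol, fits to genes with whole reads, and the count of genes 2-fold between stages in wild type and Cmi depletion without the Trr libraries. The fit was tested on simulated data with 50 changed genes at each size among 11467. It recovered 10%, 50%, 66% and 80% of genes changed by 1, 2, 3 and 4 on the log2 scale in Cmi depletion, with 4 false calls among 11267 unchanged genes, and 34%, 82%, 88% and 94% for stage, with 3 false calls. Loading and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Coverage along genes and alternative transcripts are not analysed here, since the deposited table gives 1 value per gene.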

Results

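RNA from whole wandering larvae of Drosophila melanogaster, in the last instar, was sequenced from 3 genotypes at 2 stages, with 1 library for each of the 6 groups. The genotypes were wild type, larvae expressing a short hairpin RNA against Cmi (gene Lpt), and larvae expressing 1 against Trr (gene trr). Both hairpins were expressed with the GawB69B Gal4 driver. Cmi and Trr are subunits of a COMPASS-like complex that methylates histone H3 at enhancers. The blue gut stage is the earlier and the clear gut stage the later part of wandering, as the ecdysone pulse before metamorphosis builds up. The 6 libraries hold 23.1, 23.6 and 23.3 M reads on genes at blue gut and 24.2, 25.0 and 23.9 M at clear gut, for wild type, Cmi depletion and Trr depletion. The 10 most abundant genes took 19.4%, 17.8% and 17.9% of the reads at blue gut and 11.8%, 13.4% and 13.0% at clear gut. No group has a replicate, so the spread between pools of the same genotype and stage is unknown. Values are RPKM, with log2 ratios of RPKM + 1, and intervals are exact 95% counting intervals.

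The genes targeted by the hairpins were compared first, to see whether each was lower in its own depletion. Lpt was lower in both Cmi depletion libraries, by less than 1.5-fold, while trr was higher than wild type in the Trr depletion library at blue gut and lower at clear gut. Lpt (gene 37795, dm6 chromosome 2R, 23898561 to 23903661) measured 5.57 RPKM in wild type and 4.44 in Cmi depletion at blue gut, a ratio of 0.797 (0.705 to 0.9003). At clear gut it measured 6.66 and 5.11, a ratio of 0.767 (0.687 to 0.856). In the libraries labelled Trr depletion, Lpt stood at 1.07 (0.953 to 1.197) and 1.04 (0.942 to 1.16) times wild type, not distinguishable from wild type at this depth. The gene trr (gene 31149, chromosome X, 1881313 to 1889950) measured 2.92 RPKM in wild type and 3.60 in the library labelled Trr depletion at blue gut, a ratio of 1.23 (1.10 to 1.38) against the direction of the label. At clear gut it measured 6.19 and 4.76, a ratio of 0.769 (0.705 to 0.838). In Cmi depletion trr stood at 1.53 (1.38 to 1.71) times wild type at blue gut and 0.958 (0.884 to 1.04) times at clear gut. In the additive limma fit the mean log2 ratio of Lpt in Cmi depletion was -0.30 and that of trr in the libraries labelled Trr depletion -0.05, and limma called neither gene. With median-ratio scaling and quantile normalization these means were -0.40 and -0.43 for Lpt, and -0.18 and -0.25 for trr. Between the depletions, trr was lower in the libraries labelled Trr depletion at both stages. It measured 3.60 against 4.49 RPKM in Cmi depletion at blue gut and 4.76 against 5.925 at clear gut. With 1 library per group, a raised value in the Trr blue gut library and a low value in wild type cannot be told apart. Because trr at blue gut goes against its label when set against wild type, the Trr libraries are named below by their label only.

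**Figure D1:**
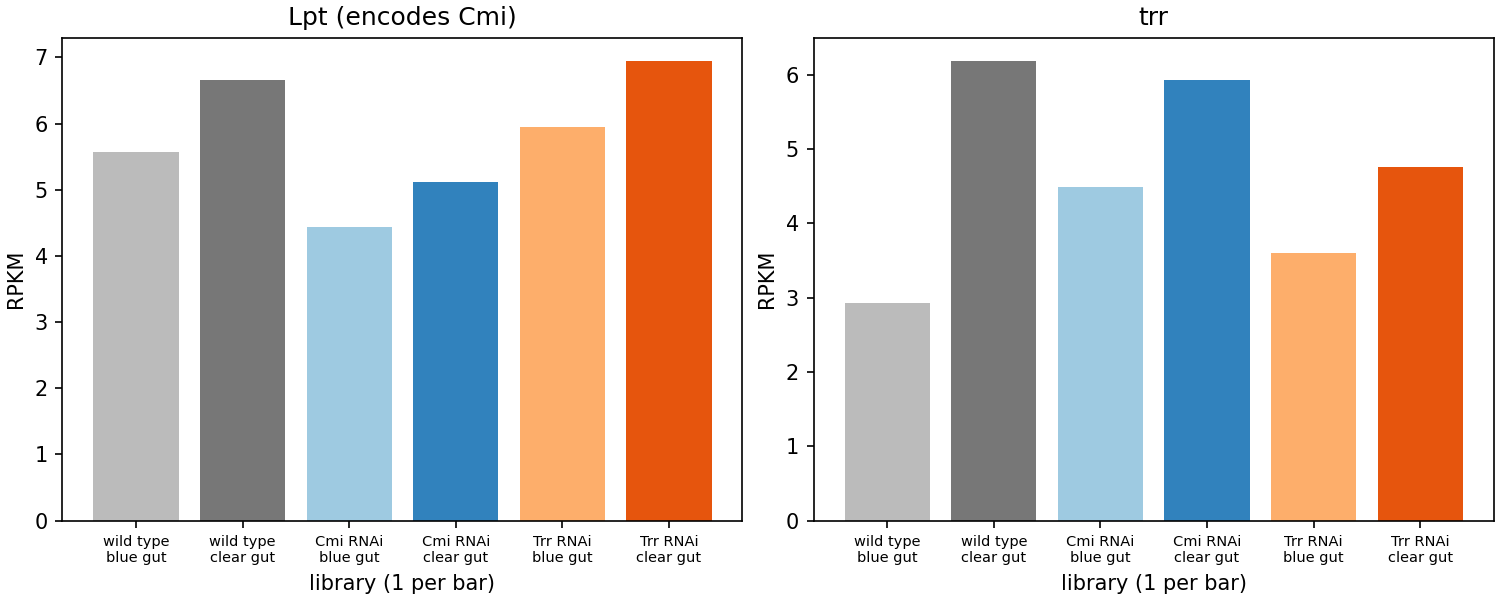
RPKM of Lpt (Cmi) and trr in each of the 6 libraries, 1 bar per library, with the vertical axis from 0. Lpt is lower than wild type in both Cmi depletion libraries (4.44 and 5.11 against 5.57 and 6.66), and trr is lower than wild type in the library labelled Trr depletion at clear gut (4.76 against 6.19) but not at blue gut (3.60 against 2.92).

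The COMPASS subunits, which include the catalytic subunits and their shared partners, had higher values at clear gut than at blue gut in 15 of 16 cases, and limma called 0 of them in either depletion. Utx, the histone H3 lysine 27 demethylase of the COMPASS-like complex, rose from 12.3 to 36.3 RPKM in wild type between the stages, with a log2 change of 1.16 (SE 0.15, adjusted p = 0.0088, limma) and the same direction in 3 of 3 genotypes. Of the 16 subunits tested, limma called 5 higher at clear gut and 0 lower over all genes, and 7 higher when adjusted over the list alone. The others called over all genes were Set1 (0.80), Hcf (0.75), Mnn1 (0.65) and Ncoa6 (0.89). These 4 calls end with median-ratio scaling, at adjusted p = 0.0702, 0.0738, 0.119 and 0.113. The list's median at clear gut was 0.45 (camera adjusted p = 0.0333, and adjusted p = 0.621 with an estimated correlation), and the call also ends with median-ratio scaling, at an adjusted p of 0.0774. Of the 16, 1 in Cmi depletion and 0 in the libraries labelled Trr depletion had an unadjusted p below 0.05, and the camera adjusted p of the list was 0.25 and 0.964.

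Clear gut was compared with blue gut over the 3 genotypes, to follow the programme of late wandering. The tanning enzyme genes ebony and ple and uncharacterised genes such as CG34193 rose by large factors, while midgut digestive, fat body, larval cuticle and muscle genes fell as lists. Camera lost these 4 list calls with an estimated correlation (adjusted p = 0.621 for each), a setting that hardly any list can pass with 2 residual degrees of freedom. The ecdysone-induced nuclear receptors Eip78C, Hr4 and Hr46 rose together. Genes of cell death and autophagy also rose, a list call lost in the same way. The pale gene ple, which encodes tyrosine hydroxylase, went from 5.90 to 1830 RPKM in wild type, from 7.25 to 1908 in Cmi depletion and from 7.69 to 871 in the libraries labelled Trr depletion. The storage protein Lsp1beta went from 7387 to 253, from 6707 to 124 and from 5967 to 269 RPKM.

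In all, limma called 4052 of 11467 genes, 2777 higher and 1275 lower at clear gut, and 1885 of these changed at least 2-fold. As deposited, the median of all genes lay 0.15 higher at clear gut on the log2 scale, and it lay at -0.06 with median-ratio scaling and 0.04 with quantile normalization. The split follows this shift, with 1307 higher and 1467 lower under median-ratio scaling and 2117 higher and 1414 lower under quantile normalization. Of the 4052 genes, 2559 and 3314 were also called under these scalings. Limma called 0 genes without the wild-type library at either stage, 2622 without the blue gut and 2564 without the clear gut library labelled Trr depletion.

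The highest genes by the smallest change in the 3 genotypes were CG34193 (log2 9.02, SE 0.15, adjusted p = 0.000529), CG14664 (8.88), CG7924 (9.52), CG7906 (8.92), ebony, CG34244 (8.66), CG34206 (8.02) and ple (7.52, SE 0.30, adjusted p = 0.00256). CG34193 went from 0.484 to 894 RPKM in wild type, from 0.316 to 724 in Cmi depletion and from 0.320 to 550 in the libraries labelled Trr depletion. In the list of 23 chitin and epidermal genes, limma called 13 higher and 1 lower, the same counts as when adjusted over the list alone. The largest of these were the tanning enzymes e (ebony, 8.35), ple, b (black, 5.75) and Ddc (dopa decarboxylase, 3.99). The list's median was 1.01 (camera adjusted p = 0.0197, and adjusted p = 0.621 with an estimated correlation). Of the 8 pupal cuticle genes limma called 3 higher, among them Cpr49Ac (2.43), and 1 lower, against 3 and 3 when adjusted over the list alone. Camera did not call this list (adjusted p = 0.667), and its direction in that test was lower although its median was 0.34.

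The lowest genes by the same rule were CG9468 (log2 -6.71), CG9466 (-6.43), Lcp65Ab1 (-6.85), LysS (-6.44), CG6839 (-5.87), CG11911 (-5.84), Lsp1beta (-5.03, SE 0.27, adjusted p = 0.0027) and CG3819 (-5.88). CG9468 and Lcp65Ab1 have values with 0.5 of a read. Digestive enzymes of the midgut had a median of -3.22, with 38 of 43 called lower and 2 higher (39 and 2 when adjusted over the list alone), among them the lysozymes LysS, LysD (-5.70) and LysB (-5.02) and the trypsin thetaTry (-5.06). Larval cuticle genes had a median of -2.95, with 11 of 16 lower and 1 higher (13 and 1 over the list alone). Muscle genes had a median of -1.88, with 12 of 21 lower and 1 higher (15 and 1 over the list alone), among them the myosin heavy chain Mhc, which fell from 141 to 4.79 RPKM in wild type, from 239 to 1.80 in Cmi depletion and from 129 to 17.5 in the libraries labelled Trr depletion. Fat body genes had a median of -0.45, with 7 of 14 lower and 1 higher (7 and 2 over the list alone), led by Lsp1alpha (-5.03), Lsp1beta and Lsp1gamma (-3.96). In the order midgut, larval cuticle, muscle and fat body, camera gave adjusted p = 6.36e-22, 3.42e-08, 1.23e-07 and 4.4e-04, and for each adjusted p = 0.621 with an estimated correlation.

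Metabolic genes had lower values at clear gut. All 13 glycolytic genes were called lower, over all genes and over the list alone, with a median of -1.30 and Pglym78 (-2.10), Gpdh (-2.03), Ald (-1.72) and Pgi (-1.64) as the largest. Respiratory chain genes had a median of -0.45 and 33 of 82 called lower, also over the list alone, among them RFeSP (-0.84) and Cyt-c-p (-0.80). Lipid genes had a median of -0.51, with 9 of 18 lower and 2 higher under both adjustments, among them the lipase mag (-3.84), the fatty acid synthase CG3523 (-2.91) and the desaturase desat1 (-1.94). Cytochrome P450 genes had a median of -1.20, with 40 of 63 lower and 5 higher (45 and 5 over the list alone), and glutathione S-transferases a median of -0.38, with 10 of 30 lower and 2 higher (11 and 2 over the list alone). In the order glycolysis, respiratory chain, lipid, P450 and transferases, camera gave adjusted p = 1.11e-09, 1.59e-14, 1.37e-05, 1.23e-16 and 1.38e-04, and for each adjusted p = 0.621 with an estimated correlation. Ribosomal protein genes were called by camera (median -0.11, adjusted p = 4.15e-05, and adjusted p = 0.664 with an estimated correlation) with 0 single genes called by limma under both adjustments and 1 at an unadjusted p below 0.05, and their median turns to 0.14 with quantile normalization. Mitochondrial ribosomal protein genes had a median of -0.05 (adjusted p = 0.0049, and adjusted p = 0.713 with an estimated correlation), with 1 of 66 called higher and 0 over the list alone.

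Genes of the early ecdysone response, which the steroid pulse switches on, rose with a median of 1.58, with 19 of 25 called higher and 2 lower (20 and 2 over the list alone). Camera lost this list call with an estimated correlation (adjusted p = 0.621). Eip78C went from 0.813 to 41.8 RPKM in wild type (log2 4.37 over the 3 genotypes, SE 0.20, adjusted p = 0.00256), and Hr4 (4.15), Hr46 (3.85) and ImpE2 (3.53) followed. The transcription factors br (1.94), Eip74EF (2.17) and Eip75B (1.54, adjusted p = 0.0427) also rose, with the call of Eip75B ending under median-ratio scaling (adjusted p = 0.104) and quantile normalization (adjusted p = 0.071). The receptor gene EcR was not called (-0.20, adjusted p = 0.72). It went from 12.8 to 17.4 RPKM in wild type, from 18.1 to 7.33 in Cmi depletion and from 18.6 to 21.3 in the libraries labelled Trr depletion. The 6 late Eig71E genes had a median of 2.99, with Eig71Eg (3.83) called and 4 called over the list alone. All 24 genes of cell death and autophagy were higher, 19 of them called under both adjustments (median 0.79), among them Atg7 (2.75), rpr (1.95), Nc (1.87) and Ark (1.73). For the early ecdysone, Eig71E and cell death lists camera gave adjusted p = 2.94e-05, 0.0344 and 4.76e-05, and for each adjusted p = 0.621 with an estimated correlation. The Eig71E call ends with a pseudocount of 0.1 (adjusted p = 0.0514).

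Patterning and chromatin genes had higher values at clear gut. Imaginal disc genes rose with a median of 0.80, with 37 of 46 called higher and 1 lower (44 and 1 over the list alone), among them hth (1.48) and wg (1.21). Camera lost this list call with an estimated correlation (adjusted p = 0.621). Polycomb group genes, which keep genes silent, had 13 of 22 called higher (17 over the list alone) and a median of 0.60, with jing (1.74), Psc (1.15) and ph-p (1.12). Hippo pathway genes had 12 of 16 called higher (13 over the list alone) and a median of 0.86, and Enhancer of split genes 8 of 12 higher and 1 lower under both adjustments, with a median of 0.63 and Kaz-m1 (-3.59) as the lower gene. In that order camera gave adjusted p = 7.87e-08, 4.28e-04, 7.97e-04 and 0.0252, and for each adjusted p = 0.621 with an estimated correlation. Blood cell genes fell with a median of -0.53 (adjusted p = 0.012, ending at 0.0803 with median-ratio scaling, and adjusted p = 0.621 with an estimated correlation). Of the 17, limma called 9 lower and 5 higher (10 and 6 over the list alone), among them nimB2 (-2.33) and Hml (-2.12).

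**Figure D2:**
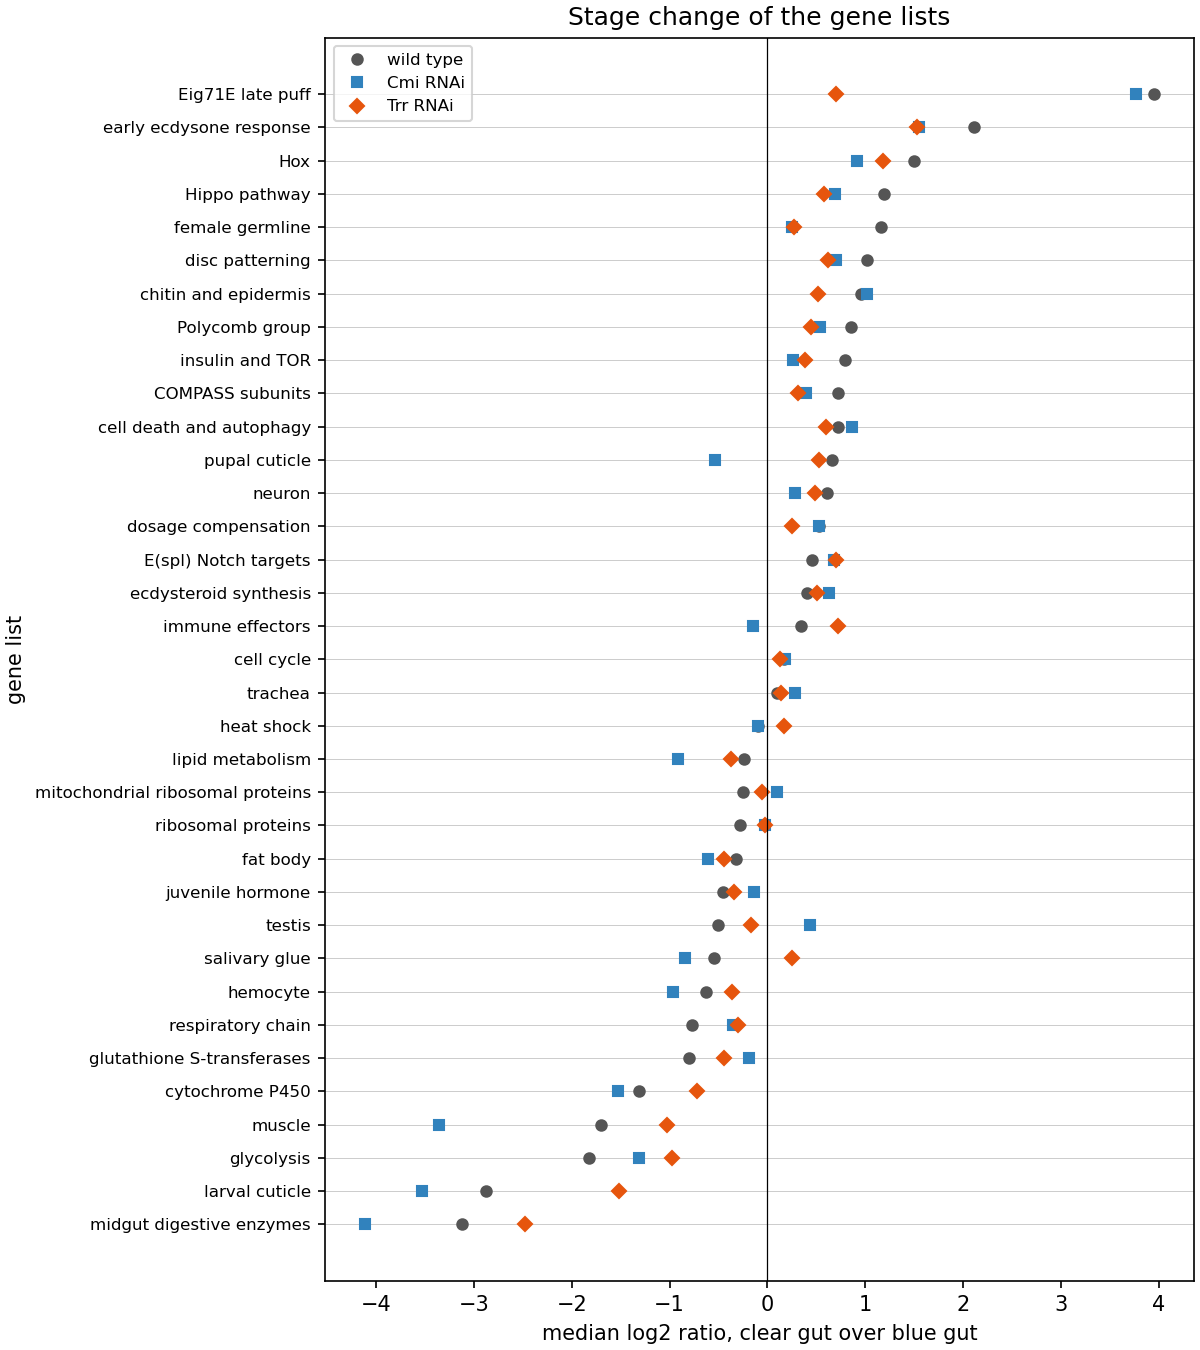
Median log2 ratio of clear gut to blue gut for the 35 gene lists (horizontal axis, log2 of RPKM + 1) in each of the 3 genotypes, 1 point per genotype and list. Over the 3 genotypes, midgut digestive and larval cuticle genes have the lowest medians (-3.22 and -2.95) and late Eig71E genes the highest (2.99); the medians of cell cycle, heat shock and immune genes turn sign with median-ratio scaling and that of ribosomal protein genes with quantile normalization.

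The size of the stage change was compared between genotypes. Fewer genes differed 2-fold between the stages in the libraries labelled Trr depletion (791 higher and 774 lower) than in wild type (1698 and 1060) or Cmi depletion (995 and 1189), a difference that was not tested for want of replicates. In all 3 genotypes 538 genes were higher and 642 lower, and 852 and 878 in wild type and Cmi depletion without the Trr libraries, a count added after seeing the data. The split between higher and lower follows the scaling, with 1361 and 1307 in wild type, 592 and 1454 in Cmi depletion and 605 and 867 in the libraries labelled Trr depletion under median-ratio scaling. Across genes, the stage change of wild type correlated with that of Cmi depletion (Pearson 0.844, Spearman 0.687) and of the libraries labelled Trr depletion (0.863 and 0.841). The slope on the wild-type change was 0.902 for Cmi depletion (1.26 from the reverse regression) and 0.647 for the libraries labelled Trr depletion (0.869 from the reverse regression). Mlc1, a myosin light chain, went from 308 to 17.8 RPKM in wild type, from 321 to 4.79 in Cmi depletion and from 226 to 44.4 in the libraries labelled Trr depletion. Hsp23, a small heat shock gene, rose over the 3 genotypes (log2 3.31), from 452 to 4073, from 411 to 4211 and from 323 to 3446 RPKM.

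Cmi depletion was compared with wild type, to find genes whose expression depends on the COMPASS-like complex. Cyp12a4, a mitochondrial cytochrome P450 linked to insecticide resistance, rose many fold, and Pgd, an enzyme of the pentose phosphate pathway, rose from at most 1 read in wild type. Dcr-2, the Dicer that makes small interfering RNAs, rose several fold, and the metallothionein gene MtnC and the glutathione transferase gene GstE3 fell. Glue genes of the salivary gland, cuticle genes and blood cell genes had lower values as groups, list calls of camera that are lost with an estimated correlation (adjusted p = 0.893 for each).

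Over both stages limma called 12 genes, 10 higher and 2 lower, of which 6 have no gene symbol. Cyp12a4 (gene 42294, chromosome 3R, 19135158 to 19137136) measured 3.06 RPKM in wild type and 64.9 in Cmi depletion at blue gut, a ratio of 21.2 (17.7 to 25.6), and 1.65 and 42.7 at clear gut, a ratio of 26.0 (20.4 to 33.6), with a log2 change of 4.03 (SE 0.14, adjusted p = 0.00967). Pgd (gene 31185, chromosome X, 2145136 to 2148566) had 1 and 0 reads in wild type and 411 and 375 in Cmi depletion. Its ratio was 396 (71.8 to 1.593e+04) at blue gut and at least 121-fold higher at clear gut, against a floor of 3 reads in the wild-type library (the exact lower limit, 97.7, allows a smaller fold; log2 3.22, SE 0.17, adjusted p = 0.0237). Rack1, a ribosome-associated scaffold, had 148 and 183 reads in wild type and 2541 and 2559 in Cmi depletion, folds of 16.8 and 13.5 (log2 3.66, SE 0.15, adjusted p = 0.0141), and its values include 0.5 of a read. Dcr-2 (gene 36993, chromosome 2R, 17574979 to 17581525) measured 14.3 and 29.3 RPKM in wild type and 143 and 197 in Cmi depletion, ratios of 9.95 (9.49 to 10.4) and 6.74 (6.52 to 6.96), with a log2 change of 2.97 (SE 0.18, adjusted p = 0.036). MtnC went from 34.5 to 2.79 and from 21.5 to 1.97 RPKM (log2 -3.07, SE 0.20), and GstE3 from 221 to 51.3 and from 78.4 to 15.2 (log2 -2.19, SE 0.13), each with an adjusted p of 0.036. The call of Dcr-2 ends with median-ratio scaling (adjusted p = 0.0568), that of MtnC with quantile normalization (0.0556), that of GstE3 with both (0.0509 and 0.0613) and that of Pgd at a mean of at least 5 RPKM (0.0691), and 1 of the 12 genes, without a symbol, stays called in a model without the stage term. The calls of Dcr-2, MtnC and GstE3 also end with no filter on low values (limma adjusted p = 0.0513 for each). In fits added after seeing the data, they end over entries with a gene symbol (0.0538, 0.0557 and 0.0538). Over genes with whole reads they end as well (0.0596, 0.0602 and 0.0596), as does that of Pgd (0.0596). With quantile normalization limma called 7 genes, 7 higher and 0 lower. The larger side turns in a fit to the wild-type and Cmi libraries alone, which called 6 higher and 9 lower and shared 8 of the 12 genes. It also turns without either library labelled Trr depletion, with 6 higher, 8 lower and 7 shared each time, and without the blue gut library of Cmi depletion, with 52 higher and 276 lower. Limma called 0 genes without the wild-type library of either stage, 328 without the blue gut and 68 without the clear gut library of Cmi depletion, and 1 over genes with whole reads alone, a fit added after seeing the data, while 781 genes had an unadjusted p below 0.05 with all 6 libraries.

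At least 2-fold at both stages, 50 genes were higher and 121 lower in Cmi depletion, where independent lists would share 2.9 and 10.7. In opposite directions at the stages went 10, against 12.5 for independent lists. At blue gut alone 213 were higher and 251 lower, and at clear gut alone 158 and 489. Among the highest by the smaller of the ratios was CG5953 (36.5 to 494 and 99.0 to 586 RPKM, adjusted p = 0.0863), beside the 4 named higher genes and 5 entries without a symbol. Lowest by the same rule was Victoria (TotE in the reference), of the Turandot family of stress genes, with 452 and 2723 reads in wild type and 0 and 10 in Cmi depletion. That is at least 154-fold lower at blue gut against the floor of 3 reads, where the exact upper limit of the ratio (0.00802) allows a smaller fold. At clear gut the ratio was 0.00354 (0.0017 to 0.00653), with an adjusted p of 0.131 in limma. Next were MtnC, CG6870 (89.7 to 12.03 and 43.0 to 2.09 RPKM), CG43315, the glue gene Sgs5, the larval cuticle gene Lcp65Ac (109 to 16.4 and 13.4 to 1.01), CG10918, CG17105 (894 to 154 and 55.4 to 1.44) and CG14852, and 1 entry without a symbol. Of these, MtnC alone was called.

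Camera called 16 of the 35 lists in Cmi depletion, 4 higher and 12 lower, and 0 with an estimated correlation (adjusted p = 0.893 for each of the 16). The median of all genes lay 0.13 higher than in wild type as deposited and 0.03 higher with median-ratio scaling. Glue genes had 9 of 9 members lower, 0 called by limma over all genes, 3 when adjusted over the list alone and 4 at an unadjusted p below 0.05 (median -1.93, camera adjusted p = 2.14e-08, and adjusted p = 0.893 with an estimated correlation). Their medians at blue and clear gut were -1.50 and -2.19, each at percentile 0 among random lists. That rank leaves out the correlation between members, estimated at 0.74 for this list. Sgs5 went from 6576 to 1011 and from 6421 to 750.1 RPKM (adjusted p = 0.15), and Sgs8 from 3254 to 460.2 and from 2625 to 576 (adjusted p = 0.1). Pupal cuticle genes (8 of 8 lower, 0 called, 2 over the list alone and 2 at an unadjusted p below 0.05, median -0.92) and larval cuticle genes (12 of 16 lower, 0 called, 1 over the list alone and 4 at an unadjusted p below 0.05, median -0.62) had camera adjusted p = 9.04e-07 and 1.18e-05, and for each adjusted p = 0.893 with an estimated correlation. Blood cell genes had 13 of 17 lower, with 0 called under both adjustments and 6 at an unadjusted p below 0.05 (median -0.30, camera adjusted p = 1.44e-07, and adjusted p = 0.893 with an estimated correlation). The prophenoloxidases of crystal cells, proPO45 and proPO-A1, went from 281 to 103 and from 181 to 64.4 RPKM at blue gut, and from 91.4 to 3.99 and from 74.0 to 3.84 at clear gut (adjusted p = 0.516 and 0.515).

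Ecdysteroid synthesis genes, active in the prothoracic gland, had medians of -0.31 at blue gut (percentile 0.22) and -0.30 at clear gut (percentile 0.09). Of the 12, limma called 0 over all genes, 1 higher and 3 lower when adjusted over the list alone, and 4 had an unadjusted p below 0.05 (camera adjusted p = 0.00208, and adjusted p = 0.893 with an estimated correlation). The enzyme genes spok and phm measured 19.3 and 22.6 RPKM in wild type and 9.89 and 12.1 in Cmi depletion at blue gut, and 29.1 and 26.3 against 20.2 and 19.4 at clear gut. Ptth, which encodes the peptide that stimulates the gland, measured 1.58 and 3.41 RPKM at blue gut and 1.43 and 3.60 at clear gut. Cell cycle genes (34 of 34 higher, median 0.23), Polycomb group genes (22 of 22 higher, median 0.25) and imaginal disc genes (43 of 46 higher, median 0.25) had 0 members called under both adjustments, 1 cell cycle gene and 0 of the others at an unadjusted p below 0.05, and camera adjusted p = 0.00124, 0.00536 and 0.00536, and for each adjusted p = 0.893 with an estimated correlation. Against random lists, the imaginal disc and Polycomb group medians were high at blue gut alone, at 0.40 (percentile 100) and 0.42 (percentile 99.97), with 0.08 (percentile 3.29) and 0.16 (percentile 54.3) at clear gut. Both clear gut medians turn sign with median-ratio scaling, to -0.10 and -0.03, and the disc median also with quantile normalization. Ribosomal protein genes had 75 of 80 lower (median -0.16, camera adjusted p = 5.55e-11, and adjusted p = 0.893 with an estimated correlation) and 0 called under both adjustments or at an unadjusted p below 0.05. Their median was -0.04 with quantile normalization, and by stage -0.29 (percentile 0.01) at blue gut and -0.04 (percentile 85.2, with 29 of 80 higher) at clear gut. The clear gut median turns to 0.06 with quantile normalization. The other called lists were cytochrome P450 genes (median -0.18, 1 called higher; 1 higher and 2 lower over the list alone), glutathione transferases (-0.07, 1 called lower; 2 lower over the list alone), midgut enzymes (-0.13, 0 called; 1 lower over the list alone), muscle (-0.28), chitin and epidermis (-0.04), respiratory chain (-0.05) and testis genes (0.26), the last 4 with 0 called under both adjustments. Their camera adjusted p were 7.44e-05, 2.29e-04, 7.55e-04, 0.00371, 0.00804, 0.0169 and 0.0288 in that order, and for each adjusted p = 0.893 with an estimated correlation. For respiratory chain genes the mean was 0.01, above 0, while the median and the test were lower, and the medians by stage were -0.28 at blue gut and 0.14 at clear gut (-0.07 with median-ratio scaling). P450 genes had a median of 0.00 at blue gut (32 of 63 higher) and -0.24 at clear gut, and transferases -0.26 at blue gut and 0.00 at clear gut (15 of 30 higher). The transferase median at clear gut was -0.20 with median-ratio scaling. Those of muscle, midgut and testis genes also differ in sign between the stages and are given below.

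The libraries labelled Trr depletion were compared with wild type for the same question, with the reservation that trr itself was lower than wild type at clear gut alone. Cyp12a4, Pgd and Rack1 rose in these libraries as well. The values of Cyp12a4 were above those in Cmi depletion at both stages, a difference that limma did not call (log2 1.34, SE 0.14, adjusted p = 0.327). Dcr-2 stood at 1.2 times wild type at blue gut and 0.873 times at clear gut. The prophenoloxidases and Victoria had lower values at both stages, and the larval cuticle gene Lcp3 higher values at both.

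Over both stages limma called 6 genes, all higher, of which 3 have no gene symbol, and 789 genes had an unadjusted p below 0.05. Cyp12a4 measured 155 and 117 RPKM, ratios of 50.5 (42.2 to 61.0) at blue gut and 71.4 (56.2 to 92.1) at clear gut, with a log2 change of 5.37 (SE 0.14, adjusted p = 0.0027). Pgd had 468 and 443 reads, a ratio of 457 (83.0 to 1.838e+04) at blue gut and at least 149-fold higher at clear gut against that floor (the exact lower limit, 121, allows a smaller fold; log2 3.45, SE 0.17, adjusted p = 0.0213). Rack1 had 2259 and 2146 reads, folds of 15.2 and 11.8 (log2 3.50, SE 0.15, adjusted p = 0.0175). The counting intervals of the ratios of Dcr-2 were 1.13 to 1.28 and 0.834 to 0.913, and limma did not call it (adjusted p = 0.95). The call of Pgd ends at a mean of at least 5 RPKM (adjusted p = 0.0828), where 3 genes are called, and 1 gene, without a symbol, is called in a model without the stage term. Limma called 0 genes without the wild-type library of either stage, 4 without the blue gut library labelled Trr depletion, 99 without the blue gut and 106 without the clear gut library of Cmi depletion, 104 in a fit to the wild-type and Trr libraries alone, and 2 over genes with whole reads alone, a fit added after seeing the data.

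At least 2-fold at both stages, 71 genes were higher and 50 lower in the libraries labelled Trr depletion, where independent lists would share 4.6 and 3.2. In opposite directions at the stages went 33, against 8.4 for independent lists. Under median-ratio scaling 52 were higher and 75 lower at both stages, and under quantile normalization 58 and 77, so that the larger side turns with the scaling. Highest by the smaller of the ratios was Lcp3, from 20.3 to 2669 RPKM at blue gut and from 1.53 to 279 at clear gut (adjusted p = 0.522). CG32198 (with values at 0.5 of a read), CG32071 (47.4 to 273 and 0.731 to 49.4) and CG9877 (18.9 to 105 and 18.0 to 193) were also among them. Lowest was Victoria, with 1 read in each library against 452 and 2723 in wild type, ratios of 0.00218 (5.547e-05 to 0.0123) and 0.000373 (9.403e-06 to 0.00207), and an adjusted p of 0.18. The others were CG17105, CG43315, proPO-A1, proPO45, CG34276 (8.52 to 0.472 and 10.1 to 1.38), the cuticle gene Cpr67Fa1 (64.8 to 13.7 and 45.0 to 7.86), CG7214, CG13060 (with values at 0.5 of a read) and 1 entry without a symbol. Of these lowest genes limma called 0.

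Camera called 12 lists, 1 higher and 11 lower, and 0 with an estimated correlation. The median of all genes lay 0.15 higher than in wild type as deposited and at 0.00 with median-ratio scaling. Blood cell genes had 15 of 17 lower, 0 called by limma, 3 lower when adjusted over the list alone and 4 at an unadjusted p below 0.05 (median -0.25, camera adjusted p = 1.49e-08, and adjusted p = 0.883 with an estimated correlation). The gene proPO45 went from 281 to 53.0 RPKM at blue gut and from 91.4 to 2.90 at clear gut, and proPO-A1 from 181 to 33.5 and from 74.0 to 1.80 (adjusted p = 0.522 and 0.503). He and eater, expressed in other blood cells, went from 43.0 to 22.0 and from 26.4 to 18.6 at blue gut, and from 35.8 to 16.8 and from 16.7 to 11.2 at clear gut. Ecdysteroid synthesis genes had medians of -0.31 (percentile 0.01) and -0.35 (percentile 0) at blue and clear gut, with 0 called over all genes, 1 higher and 3 lower over the list alone and 5 at an unadjusted p below 0.05 (camera adjusted p = 4.53e-05, and adjusted p = 0.883 with an estimated correlation). Among them, spok went from 19.3 to 6.55 and from 29.1 to 10.6 RPKM, and sad from 21.4 to 12.6 and from 33.6 to 24.4. Testis genes had 35 of 35 higher, 0 called under both adjustments and 4 at an unadjusted p below 0.05 (median 0.44, camera adjusted p = 2.8e-05, and adjusted p = 0.994 with an estimated correlation). Glue genes had medians of -1.22 at blue gut and 0.20 at clear gut (-0.04 with quantile normalization), 0 called under both adjustments, 1 at an unadjusted p below 0.05, and camera adjusted p = 0.0024 (adjusted p = 0.896 with an estimated correlation), a call that ends with median-ratio scaling at 0.0529. Sgs3 went from 8406 to 3511 RPKM at blue gut and from 5564 to 3241 at clear gut.

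The other called lists were chitin and epidermis (median -0.18), larval cuticle (-0.51, with a mean of -0.03), glutathione transferases (-0.15), early ecdysone genes (-0.10), pupal cuticle (-0.20), heat shock (0.01, with a mean of -0.08), cell death and autophagy (-0.08) and cytochrome P450 genes (-0.01, with a mean of 0.14). Their camera adjusted p were 2.36e-06, 1.92e-04, 2.81e-04, 0.00238, 0.0024, 0.00569, 0.0109 and 0.0217 in that order, and adjusted p = 0.883 with an estimated correlation for each but P450 genes (adjusted p = 0.994). The P450 call ends with median-ratio scaling (adjusted p = 0.315), and the heat shock median turns to -0.10 with that scaling. The medians of early ecdysone, cell death and chitin genes were 0.17, 0.10 and 0.08 at blue gut and -0.26, -0.16 and -0.37 at clear gut, and that of P450 genes -0.09 and 0.21. Larval cuticle genes had -0.97 at blue gut and -0.01 at clear gut (8 of 16 higher), and transferases -0.21 and 0.01 (15 of 30 higher), the last turning below 0 with both other scalings. At blue gut the cell death and chitin medians turn below 0 with both other scalings. Over all genes limma called Cyp12a4 alone among the members of these lists. Over the list alone it called 1 transferase, 1 early ecdysone gene and 1 pupal cuticle gene lower and 3 P450 genes higher. Cyp4p1, a P450 gene, went from 4.75 to 23.1 RPKM at blue gut and from 0.903 to 15.1 at clear gut.

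**Figure D3:**
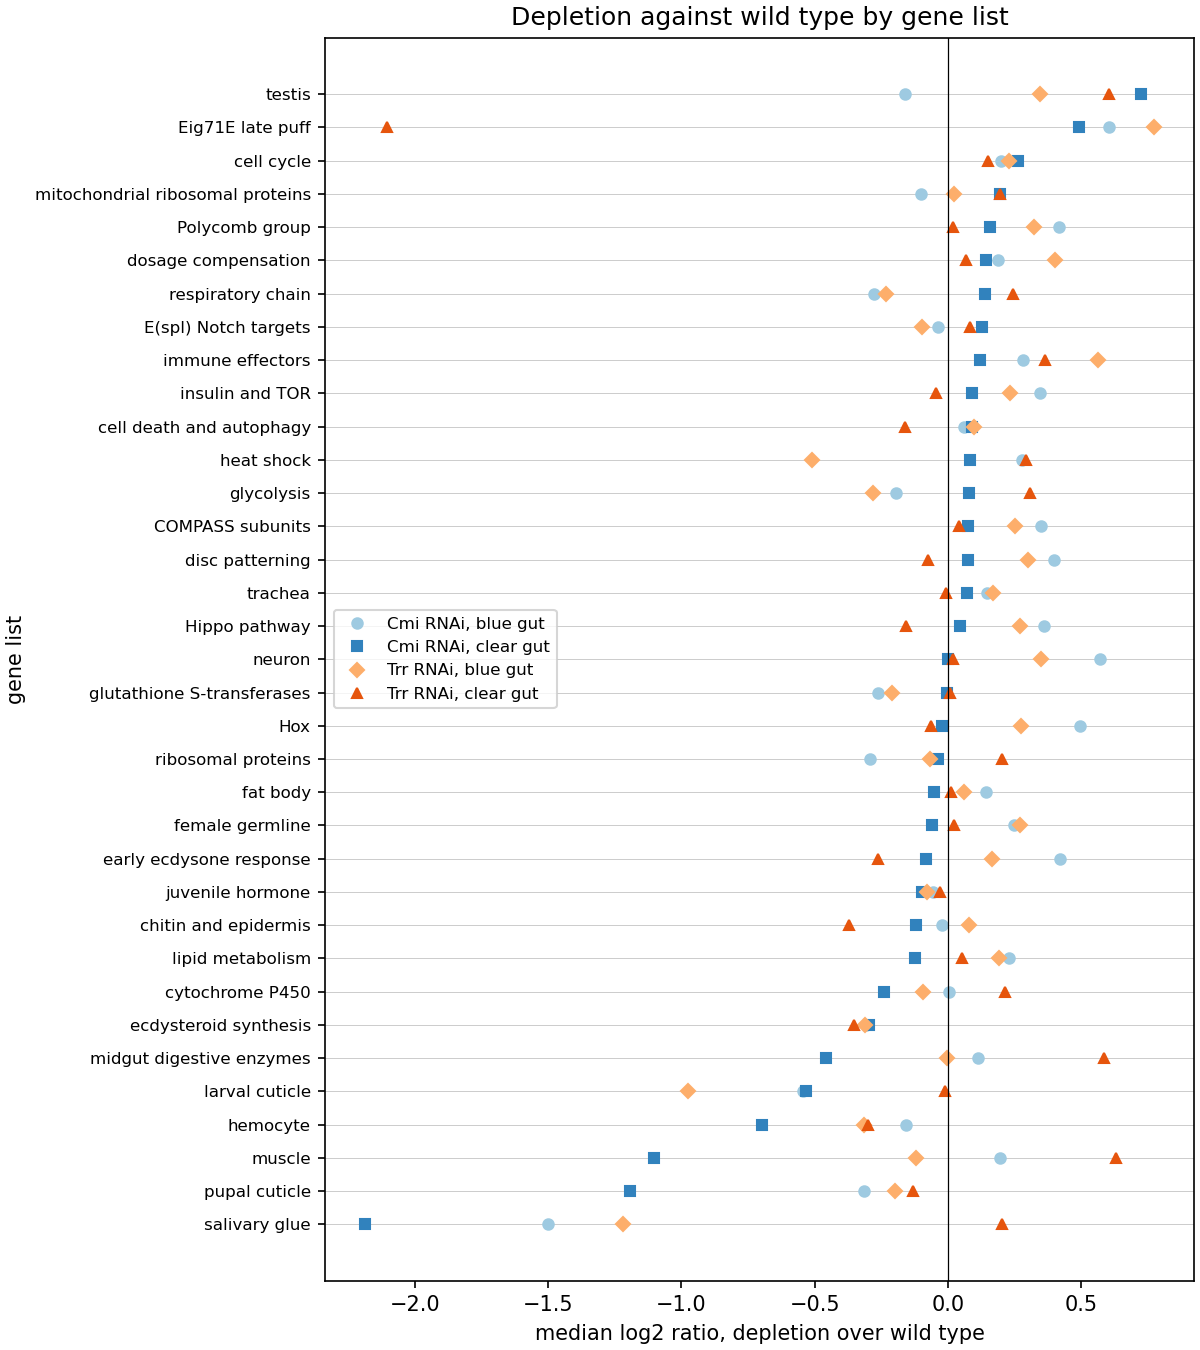
Median log2 ratio to wild type of the same stage for the 35 gene lists (horizontal axis, log2 of RPKM + 1), with 1 point for each of Cmi depletion and the libraries labelled Trr depletion at blue gut and clear gut. Glue genes have medians of -1.50, -2.19 and -1.22 in 3 of the libraries and 0.20 in the clear gut library labelled Trr depletion (-0.04 with quantile normalization), and muscle genes at clear gut have -1.10 in Cmi depletion and 0.63 in the library labelled Trr depletion.

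The depletions were then compared with each other, since Cmi and Trr act in 1 complex. Cyp12a4, Pgd, Rack1, Victoria, CG43315, CG17105 and both prophenoloxidases differed from wild type in the same direction in both Cmi depletion libraries and in both libraries labelled Trr depletion. For all of these, a difference of stock and an effect of depletion cannot be told apart, since both depletions are set against the same wild-type libraries. Dcr-2 was 143 and 197 RPKM in Cmi depletion against 17.2 and 25.6 in the libraries labelled Trr depletion, and glue genes had lower values in Cmi depletion at both stages, while muscle genes had higher values there at blue gut and lower ones at clear gut. Between the depletions limma called 0 genes, with 492 at an unadjusted p below 0.05, and the log2 difference of Dcr-2 was -2.94 (SE 0.18, adjusted p = 0.0944). Without the Cmi depletion library at blue gut limma called 337 genes, and without that at clear gut 15. CG32071 was the highest gene with a symbol by the smaller of the differences, at 273 against 51.3 RPKM at blue gut and 49.4 against 0.530 at clear gut, and 8 of the 10 genes that the rule takes have no symbol.

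At least 2-fold in the same direction at both stages and in both depletions, 30 genes were higher and 34 lower, where independent lists would share 0.31 and 0.53. Both lists share the wild-type libraries, and with no effect of genotype the simulated draws shared 16 on average over both directions and at most 29, against 64 observed. The draws hold no difference between stocks, so the excess over them does not separate stock from depletion. Of these 64, 14 of the higher and 4 of the lower have no symbol. Across genes, the ratios of the depletions at blue gut correlated at a Pearson of 0.65 (Spearman 0.612), against 0.497 in the simulation, and at clear gut at 0.373 (Spearman 0.472), against 0.50 in the simulation. Between stages, where no library is shared, the Pearson was 0.128 for Cmi depletion at blue gut with the clear gut library labelled Trr depletion (Spearman -0.17) and 0.371 (Spearman 0.281) for the other pair.

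Camera called 15 lists between the depletions, 6 higher and 9 lower in the libraries labelled Trr depletion, and 0 with an estimated correlation (adjusted p = 0.916 for each of the 15). Ribosomal protein genes (79 of 80 higher, median 0.22, adjusted p = 9.26e-12), glue genes (7 of 9 higher, median 1.37, adjusted p = 2.22e-04) and muscle genes (18 of 21 higher, median 0.82, adjusted p = 0.00868) were higher over both stages, with adjusted p = 0.916 with an estimated correlation for each. Imaginal disc genes (41 of 46 lower, median -0.12, adjusted p = 3.75e-04) and heat shock genes (16 of 18 lower, median -0.35, adjusted p = 5.16e-04) were lower, again with adjusted p = 0.916 with an estimated correlation for each. By stage, the muscle median turned from -0.34 at blue gut (18 of 21 lower) to 1.92 at clear gut (20 of 21 higher), and that of heat shock genes was -0.89 at blue gut (13 of 18 lower) and 0.06 at clear gut (11 of 18 higher, and -0.10 with quantile normalization). Among all members of these 5 lists limma called 0, and 2 glue genes were higher when adjusted over the list alone. Sgs8 measured 460.2 and 576 RPKM in Cmi depletion and 1424 and 2164 in the libraries labelled Trr depletion, at blue and clear gut.

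Whether a depletion acted differently at the 2 stages cannot be tested, since the interaction has no residual degrees of freedom, and the values are given alone. In Cmi depletion the genes with the larger deficit at blue gut were CG33267 (72.8 to 1.24 RPKM), CG42716 (30.5 to 0.522), CG43182 (34.7 to 1.18) and CG42717 (22.8 to 0.651), with ratios near 1 or values near 0 at clear gut. Those lower at clear gut relative to blue gut were CG5084 (81.3 to 0.953 at clear gut and 789 to 883 at blue gut), CG14332 (267 to 4.45 and 297 to 185), Lcp3 and CG32198. Muscle genes had a median of 0.20 at blue gut and -1.10 (percentile 0) at clear gut. Midgut enzymes had 0.11 and -0.46 (percentile 0), and testis genes -0.16 and 0.72 (percentile 100). These ranks leave out the correlation between members, estimated at 0.89 for muscle, 0.62 for midgut and 0.87 for testis genes.

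In the libraries labelled Trr depletion, CG14850 went from 39.1 to 2.31 RPKM at blue gut and from 1.23 to 8.61 at clear gut, CG7465 from 521 to 49.0 and from 1.45 to 9.81, and CG8087 from 81.6 to 0.697 and from 6.17 to 5.91. The immune genes PGRP-SB2 (0 to 0.304 at blue gut and 421 to 4.27 at clear gut), IM1 (0.333 to 64.6 and 0.955 to 0.215) and IM4 (2.08 to 27.1 and 5.58 to 0.314) went the other way, as did CG32762 (0 to 0.439 and 59.0 to 0.570). Late Eig71E genes had a median of 0.77 at blue gut and -2.10 (percentile 0) at clear gut, among them Eig71Eb, at 45.0 RPKM in wild type and 2.76 in this library at clear gut. Muscle genes had -0.12 and 0.63 (percentile 100), midgut enzymes 0.00 and 0.59 (percentile 100), and heat shock genes -0.51 (percentile 0) and 0.29, among them Hsp26 with 138 and 85.7 RPKM at blue gut and 649 and 335 at clear gut. The percentiles given here likewise leave out the correlation between members.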

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

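The tests of divided reads, of a difference in stock, of the RNA interference genes together, of scaling and of slowed development were chosen after the result was seen; the tests of neighbouring genes and of other splits of the libraries were chosen before it.

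With 1 library per group, the following differences were not tested, and each is given because its effects in the compared libraries have opposite directions. The log2 ratio of trr to wild type in the libraries labelled Trr depletion was -0.32 at clear gut and 0.23 at blue gut, a difference of -0.55. The target gene thus goes against the label at blue gut when set against wild type, while it was lower than in Cmi depletion at both stages. Late Eig71E genes had a median of -2.10 at clear gut and 0.77 at blue gut in these libraries, a difference of -2.88. Muscle genes at clear gut had a median of 0.63 in the library labelled Trr depletion and -1.10 in Cmi depletion, a difference of 1.74. In the libraries labelled Trr depletion, the clear gut minus blue gut difference was 5.71 for CG14850 (2.11 and -3.60), 5.53 for CG7465 (2.14 and -3.38) and -5.52 for IM4 (-2.32 and 3.19).

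Cyp12a4 and Pgd were higher in the Cmi depletion libraries and in those labelled Trr depletion than in wild type, where Pgd had at most 1 read. Of the 2 genes, 0 have a value with 0.5 of a read in any library. This argues against reads split evenly between near-identical entries for Cyp12a4, which had 121 and 68 reads in wild type. For Pgd, with 1 and 0 reads in wild type, such values could hardly show there. Reads given wholly to another entry would leave no such values and were not tested. Rack1, which also rose in both comparisons, has values with 0.5 of a read and was not part of this test. A stretch of chromosome missing or silent in the wild-type stock is argued against by the 10 tested genes within 20 kb of either gene, whose median log2 ratio over both depletions was 0.28. A variant of these genes in the wild-type stock and an effect of depleting the complex cannot be told apart. The labels do not name the wild-type stock, and no library is known to hold the background of the depletion stocks without a depletion. The difference of 1.34 between the libraries labelled Trr depletion and Cmi depletion in Cyp12a4, which limma did not call, holds no wild-type library. A variant in the wild-type stock therefore cannot give it, while a difference between the depletion stocks and one between the depletions cannot be told apart.

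Dcr-2 was higher in both Cmi depletion libraries and stood at 1.2 and 0.873 times wild type in those labelled Trr depletion. A joint rise of the RNA interference genes is argued against by AGO1, AGO2, Dcr-1, loqs and r2d2, whose median log2 ratio in Cmi depletion was 0.13. A change of the chromosome stretch around Dcr-2 is argued against by the 13 tested genes within 20 kb, whose median was 0.24. An effect of Cmi depletion on Dcr-2 alone and a Dcr-2 transgene in the Cmi stock, of the kind often added to strengthen RNA interference, could each give this pattern. Both stay open, since the labels do not say whether the Cmi stock carries such a transgene.

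Fewer genes differed between the stages in the libraries labelled Trr depletion. Scaling of the values is argued against as the whole cause, since the slope on the wild-type change was 0.676 with quantile normalization, against 0.647 as deposited. Noise in the wild-type change lowers such a slope, but that of Cmi depletion on the same change was 0.905 with quantile normalization. With that normalization 1546 genes differed 2-fold in the libraries labelled Trr depletion, against 2553 in wild type and 2092 in Cmi depletion. Slowed development at both stages stays open. The ratios of the blue gut library to wild type had a slope of 0.0871 on the Cmi stage change, and of 0.0927 and 0.0601 under the other scalings, where a lag would give a slope below 0. The blue gut library of Cmi depletion had nearly the same slopes on the Trr stage change (0.0724, 0.0751 and 0.0533), so that the wild-type pool they share could give this sign. A clear gut pool at an earlier point of the stage, by the time of collection or by development slowed at that stage, stays open as well. On the Cmi stage change, the ratios to wild type of the clear gut library labelled Trr depletion had slopes of -0.134, -0.137 and -0.131. These are as deposited and with median-ratio scaling and quantile normalization, and lie on the side of a lag. For the clear gut library of Cmi depletion on the Trr stage change they were 0.0765, 0.0635 and 0.0654 (Spearman -0.09, -0.11 and -0.10). Of the 21 lists that moved by at least 0.5 between stages in Cmi depletion, 15 (71.4%) lay on the blue gut side of wild type in the Trr clear gut library and 4 did in the blue gut library. With 1 pool the collection and the genotype cannot be told apart.

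The 4052 genes called between the stages were set against other splits of the 6 libraries. Of the 10 splits into 3 and 3, 1, the real one, gave as many genes, and the highest of the others gave 0. In the other splits the stage difference itself adds to the residual, so that 0 calls there are no measure of chance. Of the 10, 4 place the libraries of each genotype on opposite sides, as the real split does, and 6 do not. So few splits cannot give a share under 0.05.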

How the results depend on the processing

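Chosen after seeing the data were the fits to entries with a gene symbol, the fits to genes with whole reads and the stage counts without the Trr libraries; the other alternatives were fixed before. Of 167 values under alternatives for the results that answer a comparison, 121 stayed on their side and within their bounds. For counts this holds for the total of both directions, and the larger direction turned in 13 values, 10 of them among the 121. Genes called for the stage turned from 2777 higher and 1275 lower to 1307 and 1467 with median-ratio scaling. Genes called in Cmi depletion turned from 10 and 2 to 6 and 9 in the wild-type and Cmi libraries alone, to 6 and 8 without either library labelled Trr depletion, and to 52 and 276 without the blue gut library of Cmi depletion. Genes 2-fold at both stages in the libraries labelled Trr depletion turned from 71 and 50 to 52 and 75 with median-ratio scaling, 58 and 77 with quantile normalization and 190 and 249 at blue gut alone. Genes 2-fold between the stages in these libraries turned from 791 and 774 to 605 and 867 with median-ratio scaling, 691 and 855 with quantile normalization, 716 and 755 over symbol-bearing entries and 652 and 663 over whole-read genes. In Cmi depletion they turned from 995 and 1189 to 2731 and 1580 at 1.5-fold. The values outside their bounds follow, and the cause was not tested unless given. For the 12 genes of Cmi depletion, limma called 7 at a mean of at least 5 RPKM, 7 with quantile normalization, 3 over symbol-bearing entries, 1 over whole-read genes, 1 without the stage term and 23 at an adjusted p of 0.10, and 0 to 328 with a library left out. For the 6 genes of the libraries labelled Trr depletion it called 3 at a mean of at least 5 RPKM, 3 over symbol-bearing entries, 2 over whole-read genes, 1 without the stage term and 104 in the wild-type and Trr libraries alone, and 0 to 106 with a library left out. The 104 and the fits with a library left out have 1 residual degree of freedom in place of 2, and the lone library of a genotype or stage is then assumed to vary like the others. Between the depletions it called 5 genes at an adjusted p of 0.10, and 0 to 337 with a library left out, against 0. For the 4052 genes of the stage it called 0 to 3610 with a library left out, and 1885 with a minimum of 2-fold, which is stricter by construction. Genes 2-fold at both stages in Cmi depletion numbered 171, against 282 with a pseudocount of 0.1, 426 at 1.5-fold, 464 at blue gut alone and 647 at clear gut alone. In the libraries labelled Trr depletion they numbered 121, against 195 with a pseudocount of 0.1, 76 at a mean of at least 5 RPKM, 368 at 1.5-fold, 439 at blue gut alone and 421 at clear gut alone. A lower threshold or 1 stage alone admits more genes by construction. At 1.5-fold, 5206 genes differed between the stages in wild type, 4311 in Cmi depletion and 3198 in the libraries labelled Trr depletion. The mean log2 ratio of Lpt in Cmi depletion was -0.35 with a pseudocount of 0.1, -0.40 with median-ratio scaling and -0.43 with quantile normalization, against -0.30. That of trr in the libraries labelled Trr depletion stayed within its bounds, at -0.04, -0.18 and -0.25 in the same order, against -0.05. For these means the bound is the SD of a gene's ratios at the 2 stages. It is wide for trr, whose ratios were 0.23 at blue gut and -0.32 at clear gut, so staying within it is no sign of stability. With an estimated inter-gene correlation camera called 0 lists for Cmi depletion, 0 for the libraries labelled Trr depletion, 0 between the depletions and 0 for the stage. With 2 residual degrees of freedom hardly any list can pass that setting, so these counts do not tell which lists changed. Of 534 results on named genes, limma called 146 in the main fit, and only these can lose a call. A gene called in neither fit counts as on the same side, so most such values are of genes never called. Alternatives other than leaving out a library gave 4762 values on the same side of the threshold and 90 no longer past it. A further 43 were newly past it, and 41 changed sign without a call. Leaving out a library gave 2547, 386, 140 and 131 in the same order. The additive fit pairs the stages by genotype, with 3 pairs and 2 residual degrees of freedom. Depth limits genes near the floor of 0.0777 to 0.0842 RPKM, such as Pgd in wild type, and the missing replicates limit the genes above it as well.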

Other observations

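All values here come from comparisons fixed before the data were examined, and the members named were taken by the same rule as in the report. Single members of gene lists that camera did not call were called by limma between the stages. Among the 18 heat shock genes, whose list was not called (5 higher and 2 lower under both adjustments, camera adjusted p = 0.914), Hsp23 (log2 3.31), Hsp67Bc (2.97) and Hsp27 (2.32) were higher at clear gut and Hsp70Aa, which has values with 0.5 of a read, lower (-2.73). Among 25 immune effector genes limma called 6 higher and 2 lower under both adjustments (camera adjusted p = 0.421). Drsl5, a relative of the antifungal peptide drosomycin, went from 118 to 3042 RPKM in wild type, from 29.2 to 2868 in Cmi depletion and from 8.73 to 1251 in the libraries labelled Trr depletion (log2 6.09, SE 0.50, adjusted p = 0.00446), and PGRP-SC2 fell (-2.49). Of the 6 Hox genes tested, 5 were called higher, among them abd-A (1.64), Scr (1.57) and Abd-B (1.26), and 1 lower, under both adjustments (camera adjusted p = 0.0686, reaching 0.0198 with median-ratio scaling). Insulin and TOR pathway genes had 8 of 21 higher and 2 lower under both adjustments (camera adjusted p = 0.182), among them Sesn (1.71), the insulin receptor gene InR (1.15, a call that ends at adjusted p = 0.0525 with median-ratio scaling) and Pepck, which encodes an enzyme of glucose synthesis (-1.49). Juvenile hormone genes had 3 of 10 higher and 4 lower under both adjustments (camera adjusted p = 0.126), with Jheh3, an enzyme that breaks the hormone down, at -3.25 and CG1124 at 2.45.

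Of the remaining lists, camera called testis genes alone for the stage. Limma called 5 of 14 neuronal genes higher (6 over the list alone), among them fne (1.27) and elav (1.06), with camera adjusted p = 0.0514, which reaches 0.043 with median-ratio scaling and 0.048 with a pseudocount of 0.1. Ecdysteroid synthesis genes had 5 of 12 higher (7 over the list alone), among them kni (1.11), with camera adjusted p = 0.0771 (0.043 with median-ratio scaling). Glue genes had 1 of 9 higher and 2 lower under both adjustments, CG7587 (1.78), CG13560 (-5.17) and ng3 (-4.65), with a median of -0.10, a mean of -1.14 and adjusted p = 0.0852. Cell cycle genes had 3 of 34 higher (0 over the list alone), CycA (0.58), CycE (0.49) and CycD (0.46), and each of these calls ends with median-ratio scaling, which also turns the list's median. Female germline genes had 3 of 7 higher and tracheal genes 2 of 7 higher and 1 lower, under both adjustments, and dosage compensation genes 1 of 5 higher (3 over the list alone). Testis genes had 0 of 35 called under both adjustments and 1 at an unadjusted p below 0.05 in limma, with a median of -0.06 (camera adjusted p = 0.0329, and adjusted p = 0.735 with an estimated correlation).

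In the depletions, limma called 0 of the genes named in the rest of this part. Pepck measured 448 RPKM in wild type, 1013 in Cmi depletion and 938 in the library labelled Trr depletion at blue gut, and 79.0, 625 and 386 at clear gut. The insulin-like peptide gene Ilp2 measured 12.6, 4.54 and 4.04 at blue gut and 7.97, 3.12 and 5.58 at clear gut. Ilp8, whose peptide is made by damaged or overgrown discs, stood at 28.6 RPKM in Cmi depletion at clear gut and at most 2.19 in the other 5 libraries. Dpt, the antibacterial peptide diptericin, measured 26.9, 154 and 45.0 at blue gut and 35.0, 73.6 and 225 at clear gut. IM1 and IM2 stood at 64.6 and 78.3 RPKM in the blue gut library labelled Trr depletion and at most 1.196 and 1.91 in the other 5 libraries. The sperm genes dj, which has values at 0.5 of a read, and S-Lap1 measured 2.10 and 134 in wild type, 6.002 and 115 in Cmi depletion and 3.30 and 194 in the library labelled Trr depletion at blue gut, and 2.08 and 89.6, 9.88 and 164, and 3.54 and 162 at clear gut. The storage protein gene Lsp1gamma had higher values than wild type and Lsp1alpha lower ones. Lsp1gamma measured 10838, 13356 and 12210 RPKM in wild type, Cmi depletion and the library labelled Trr depletion at blue gut, and 218, 997 and 2126 at clear gut. Lsp1alpha measured 6347, 1193 and 2398 at blue gut and 101, 63.8 and 77.7 at clear gut. Camera called neither the insulin list (adjusted p = 0.25 and 0.859 for Cmi depletion and the libraries labelled Trr depletion) nor the immune list (0.741 and 0.964) nor the fat body list (0.396 and 0.18).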
